A study of Mus musculus with 2 samples.

How the data were processed

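RNA bound to HuR (Elavl1), an RNA-binding protein of AU-rich and U-rich transcripts, was recovered from an extract of proliferating C2C12 mouse myoblasts with a monoclonal anti-HuR antibody, and a control recovery was made from such an extract with IgG. Per the labels, the cells grew in medium with 20% serum and 1% antibiotics to 80% confluency, and the RNA was extracted with phenol and chloroform and reverse transcribed with a radiolabelled nucleotide. The array held 16896 spotted cDNA clones from 176 source plates of 96 wells, in 2 sections of 8448 features. The array's name, scanner, background correction and log base are not given in the sources used here.

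The authors deposited z scores, per the file headers: each array column had a mean of 0 and an SD of 1 within each section of the table, as checked on the values. Each antibody has 1 sample and 3 array columns, 6 in all, which carry no number, the number 3 or the number 4. Whether these runs were repeat hybridisations or separate immunoprecipitations is not stated, so they were counted as 1 sample per antibody. The mean scores of both files were identical, and the mean recomputed from the runs differed from the deposited mean by at most 0.0067. The authors also deposited a z ratio and a two-tailed p-value, as the file headers name them. The z ratio was taken as the score difference divided by the SD of all differences (0.300). How the p-value was computed is not given in the headers, and it was taken as unadjusted. Both are quoted only as the authors' values.

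Each run was centred on its median within each section. The difference of a clone is the mean over the 3 run pairs of the HuR score minus the IgG score, in z score units. Its SD is the spread between the run pairs. Runs of the same number were paired because their deviations from the antibody's mean correlated across features at 0.42, 0.55 and 0.33, against -0.48 to 0.08 for other numbers. Pairing changes the SD and leaves the mean as it is. With 1 sample per antibody no significance test between the antibodies was made and no p-value was computed.

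Comparisons used the 8450 features in the brighter 50% by mean signal. A gene's value is the median of its clones there, and its SD is that of the clones' median in each run pair. Clones were named by the Entrez Gene numbers in the deposited table, updated by number through the RefSeq genes of GRCm38.p6. Of all features, 7527 took a current symbol and 2675 kept the symbol of the table. A further 520 had conflicting numbers and 6174 had none, and these stayed unnamed. This gave 7790 genes, 4237 of them in the brighter 50%.

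The plan called for at least 2-fold changes of intensities. Because the deposited values are scores, no fold change can be given, and a centred difference of at least 1 z score unit took its place, with 0.6 and 1.5 as looser and stricter thresholds. A gene list's median was set against 10000 random lists of the same size matched on mean signal in 20 bins, and given as a percentile. Lists with at least 5 measured genes were described. The gene lists, the rule for named genes, the 2-fold rule, the filter on signal and the alternatives that do not rest on runs or positions were chosen before the data were examined. The z score threshold, the run-based alternatives, the source plate and membrane checks and the annotation groups were chosen afterwards.

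Named genes were the 15 with the highest and the 10 with the lowest clone difference in the brighter 50% whose clones all went the same way, then Hmgb1, Elavl1, Myod1, Myog and Cdkn1a, and the 2 highest and 2 lowest members of each described list. Genes named outside this rule are said to be so, and 1 gene that the rule names is not reported here. The array holds 0 features named as microRNAs, so the 4 microRNA lists had no members.

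A clone was said to have raised neighbours when the median difference of the adjoining wells on its source plate, at most 8 and without clones of the same gene, was at least 0.5. On simulated features, 2.5% of those with a true difference of 0.5, 98.0% of those with 1.5 and 99.5% of those with 2.0 reached 1, and 5 to 8 of 8250 unchanged features did. The simulated noise was drawn independently for each run from features of all signal levels. It thus holds no structure shared by runs or by neighbouring wells, and the 5 to 8 are not a count of false features in these data. Of 60 simulated lists of 20 genes among 4237 per shift, 38.33% with a shift of 0.1 and 93.33% with 0.2 lay above the 97.5th percentile. With no shift 0 did. The simulated members were drawn at random, so they lack swings that the genes of a real list share within a run. The 0 is thus not a rate of false lists in these data. The number of arrays limits the precision.

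Alternatives were quantile normalization, the scores as deposited, centring on the trimmed mean between the 10th and 90th percentile, all signal levels, the brightest 25% of features, the brightest clone of a gene, unmatched random lists, other thresholds, the median of run pairs, each run pair left out, clones without raised neighbours, a local median subtracted, each section of the array, and each member of the HuR target and high mobility group lists left out in turn. The U-rich motif comparison in 3' UTRs was left out because transcript sequences were not used here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.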

Results

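The data measured which RNAs were recovered with HuR from proliferating C2C12 cells, a mouse myoblast line that forms muscle fibres in culture when serum is withdrawn. There were 2 samples, 1 for HuR and 1 for the IgG control, each with 3 array runs. Whether the runs were repeat hybridisations or separate immunoprecipitations is not stated. Values are differences in z score units, HuR minus IgG, with the SD over the 3 run pairs. This SD is the spread between runs and cannot be taken as the spread between independent immunoprecipitations. Across features, runs of the HuR sample correlated at 0.80 to 0.87 and those of the IgG sample at 0.77 to 0.88. The differences between HuR and IgG, on which the results rest, correlated far less between run pairs, at 0.03 (unnumbered pair and pair 3), 0.31 (unnumbered pair and pair 4) and 0.10 (pairs 3 and 4). The mean scores of both samples correlated at 0.95, so the ranking of features was much alike with HuR and IgG. Because each column was scaled to an SD of 1, this does not tell how much of the recovered RNA was shared.

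The comparison asks which transcripts were enriched in the HuR complex. Actb, which encodes cytoplasmic beta-actin (Entrez Gene 11461), was higher in the HuR immunoprecipitate on each of its 8 clones, with a gene difference of 2.21 ± 0.39 (SD over 3 run pairs) and clones from 1.47 to 2.66. Hmgb1, which encodes a high mobility group chromatin protein (Entrez Gene 15289), was higher by 1.51 ± 0.43, and its 5 clones ranged from 0.35 to 1.80. Pcbp2, which encodes a poly(C)-binding protein, was higher on both clones, by 1.64 and 1.91. Elavl1, the mRNA of HuR itself, was higher by 0.82 ± 0.12 on 1 clone. Background recovery with IgG gave scores of 2.27 to 3.37 for the Actb clones, 0.89 for Hmgb1, 0.20 for Pcbp2 and 0.16 for Elavl1.

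Other clones of the actin family were also high. Acta2, smooth muscle actin, was higher by 2.48 ± 0.35 on its 1 clone. Actg1, cytoplasmic gamma-actin, differed between clones, at 0.17 ± 0.71 and 1.87 ± 0.05. Actin genes share much of their coding sequence, so a cDNA spot need not tell them apart. Ptp4a1, a protein tyrosine phosphatase named after its values were seen, was at 1.57 and 1.72 on its 2 clones. Set, which encodes a protein partner of HuR, was at 1.04 ± 0.76, 1.12 ± 0.65 and 1.30 ± 0.05 on 3 clones. A dimmer Set clone was at 1.39 ± 0.23. The Set clones at 1.04 and 1.30 came from adjoining wells of plate 27. Of 579 genes with clones on several source plates, 4 had every clone in the brighter 50% of features at or above 1, namely Actb, Pcbp2, Ptp4a1 and Set, and 0 had every clone at or below -1. Myod1, Myog and Cdkn1a had no named clone on the array.

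**Figure D1:**
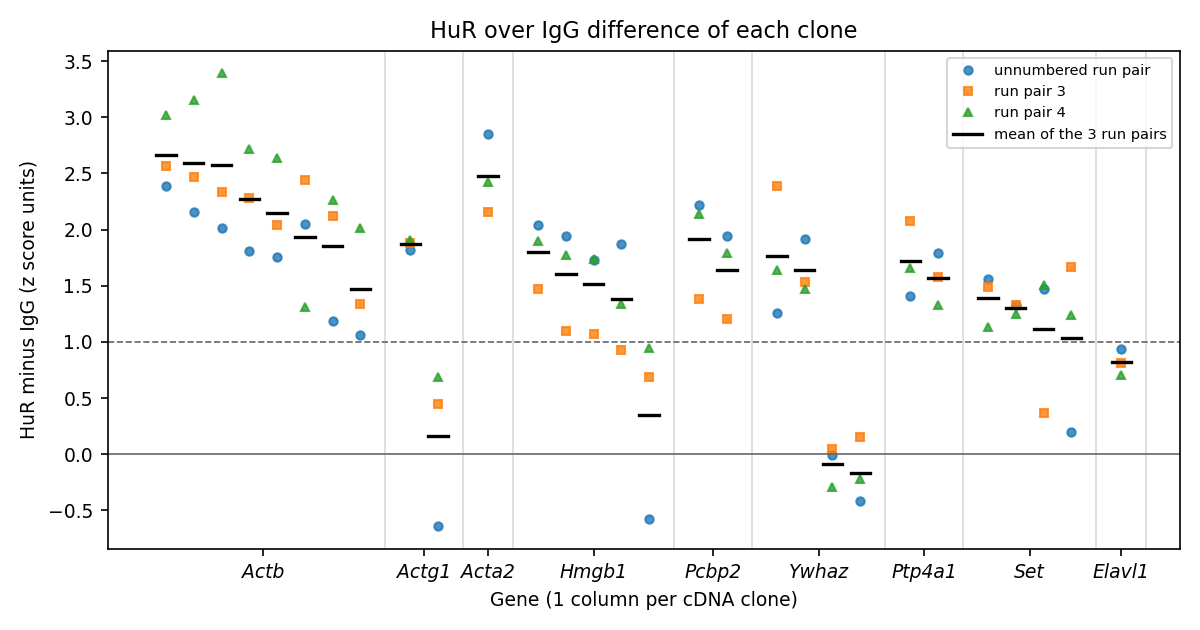
Difference between HuR and IgG in z score units (vertical axis) for each cDNA clone of 9 genes (1 column per clone). Symbols are the 3 run pairs, the bar is their mean and the dashed line marks a difference of 1. The 8 Actb clones lie between 1.47 and 2.66, and Hmgb1, Actg1, Elavl1 and Ywhaz, the last chosen after its values were seen, each have at least 1 clone below the dashed line.

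Among 8450 features in the brighter 50% by signal, 132 (1.56%) were at least 1 unit higher in the HuR immunoprecipitate. Each of the 132 was higher in every run pair, and 116 exceeded 2 SD of the run pairs. They named 83 genes on 98 features. Of the 132, 75 had raised neighbours on their source plate and 57 did not, and 75 came from 5 of the 176 plates. Only 8 features were at least 1 unit lower. None of the 8 was lower in every run pair or exceeded 1 SD, and all lay in 1 block of the array. In the authors' deposited table, 1264 of all 16896 features had a two-tailed p under 0.05, taken as unadjusted, against 845 by chance over both directions. Of the 1264, 701 were higher and 563 lower. The authors' deposited table gave z ratios of 4.90 to 8.86 for Actb, 1.18 to 6.02 for Hmgb1, 5.47 to 6.38 for Pcbp2 and 2.74 for Elavl1.

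The 15 genes with the highest clones were Actb, AV218468, Acta2, Ccnh, Fbxl5, Slc25a39, Heyl, Phip, Fgf10, Adnp, Ext2, Rbm3, Pcbp2, C79816 and Actg1. Of these, AV218468, Ccnh, Fbxl5, Slc25a39, Heyl, Adnp, Ext2 and Rbm3 rested on clones of plate 10, within a group of wells with raised neighbours around an Actb well. Ccnh, a cyclin, was at 2.47 ± 0.41 there and at 0.48 on a dimmer clone of another plate. Adnp was at 2.01 on plate 10 and at 0.12 and 0.10 elsewhere. Rbm3, a cold-inducible RNA-binding protein, was at 1.98 ± 0.22 and Heyl, a Notch target, at 2.17 ± 0.43, each on 1 clone. Fgf10 (2.05 ± 0.17) on plate 41 and C79816 (1.89 ± 0.52) on plate 45 also had raised neighbours. Phip (2.10 ± 0.35), Pcbp2 and the higher Actg1 clone did not, and Acta2 was just under the limit, with a neighbours' median of 0.49.

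**Figure D2:**
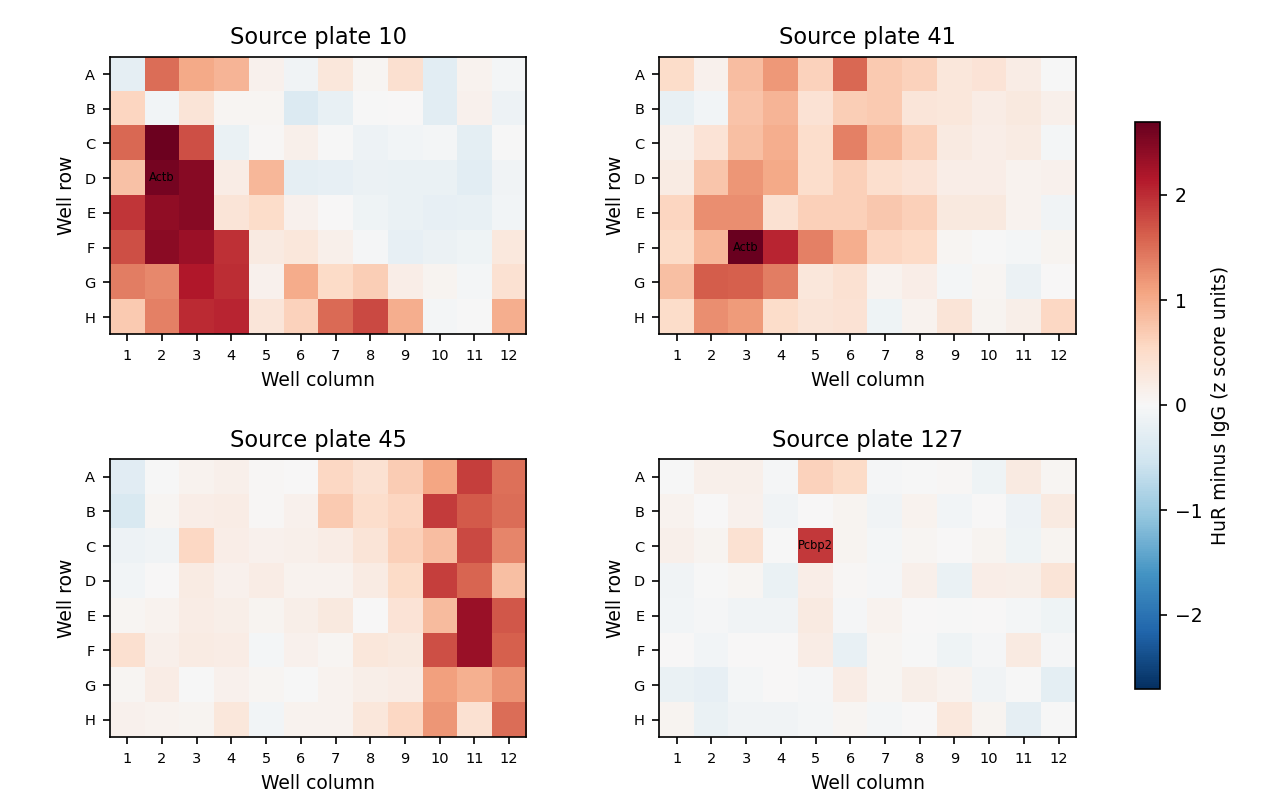
Difference between HuR and IgG in z score units (colour) by well row and column for 4 source plates of 96 wells. Wells beside Actb on plates 10 and 41 had median differences of 2.16 and 1.32, and those beside Pcbp2 on plate 127 had a median of 0.02.

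Among the 10 genes with the lowest clones were Rragc, AA407151, Cop1, Aen, AI449786, Eno1, D18Ertd451e, Zfp511 and Cmtm3. The values of these genes ran from -1.12 for AA407151 to -0.76 for Rragc. The SD over run pairs exceeded the size of the difference in each of them. Eno1, a glycolytic enolase, was at -2.29 in the unnumbered run pair, 0.26 in run pair 3 and -0.69 in run pair 4.

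Transcripts described before as HuR targets lay high as a group in the mean of the run pairs. Their 20 measured genes had a median of 0.15, at the 99.8th percentile of matched random lists, and 13 of the 20 were above 0. The median was 0.11, 0.19 and 0.17 in the unnumbered pair, pair 3 and pair 4, at percentiles 95.7, 97.3 and 99.7, so pair 4 alone lay outside the central 95% of random lists. Besides Actb and Hmgb1, the latter chosen by the study itself, Ptma (prothymosin alpha) was at 0.96 ± 0.34, Eif4e at 0.35 ± 0.24, Myc at 0.34 ± 0.25 (clones at 0.16 and 0.52, the higher with raised neighbours) and Ccnd1 at 0.31 ± 0.21. Mmp9 was at -0.81 ± 0.67 and Slc2a1 at -0.34 ± 0.69. Without Hmgb1 the median was 0.08 (97.3rd percentile), and without Hmgb1 and Actb it was 0.07 (96.7th percentile). Leaving out any 1 of the 10 upper members gave the same median as leaving out Hmgb1, and 7 of the 20 genes left out in turn gave a percentile inside the central 95%. Over all signal levels it was 0.03, at the 94.0th percentile, and without run pair 4 it was 0.09, at the 92.3rd. The values without Hmgb1, without Hmgb1 and Actb, over all signal levels and without run pair 4 lay inside the central 95%.

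The high mobility group genes had a median of 0.48 over 5 genes (99.8th percentile), led by Hmgb1 at 1.51, which the study chose, with Hmgb3 at 0.81 ± 0.47, Hmga2 at 0.11 ± 0.37 and Hmgn5 at -0.25 ± 0.50. This median was 0.66, 0.49 and 0.06 in the unnumbered pair, pair 3 and pair 4, the last at the 69.2nd percentile, and 0.11 (92.2nd percentile) over all signal levels. Without Hmgb1 it was 0.30 over 4 genes (98.1st percentile), and without Hmgb3 it lay at the 97.0th, inside the central 95%. Early response genes with AU-rich 3' ends had a median of 0.23 over 6 genes (99.6th percentile), with Myc at 0.34, Csf1 at 0.32, Nfkbia at 0.01 and Fosl1 at -0.21. Single run pairs lay at percentiles 94.3, 91.4 and 84.1, and without run pair 3 the median was 0.14 (90.9th percentile). RNA-binding proteins had a median of 0.06 over 16 genes (95.5th percentile), inside the central 95% of random lists. Run pairs lay at percentiles 96.3, 93.5 and 98.8, and the list lay outside the central 95% with the median of run pairs (98.1) and without the unnumbered pair (98.9). Their members went both ways, from Pcbp2 and Set above to Hnrnpa2b1 at -0.31 ± 0.34 and Pabpc1, the poly(A)-binding protein, at -0.40 ± 0.04. The Pabpc1 clones were at -0.40 and -0.41 in adjoining wells of plate 12 and at -0.14 ± 0.23 on plate 107. The RNA binding term of the deposited table, among the annotation groups chosen afterwards, had a median of -0.09 over 51 genes (percentile 9.42).

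The ribosomal protein, glycolytic, respiratory chain and proteasome lists lay low in the mean of the run pairs. The 67 ribosomal protein genes had a median of -0.19 (percentile 0.00), with 59 below 0, Rpl9 at -0.43 ± 0.37, Rps18 at -0.42 ± 0.45, Rpl36a at 0.17 ± 0.32 and Rps24 at 0.19 ± 0.70. Their direction differed between runs, with medians of -0.37, 0.23 and -0.43 in the unnumbered pair, pair 3 and pair 4, at percentiles 0.09, 99.99 and 0.00. Without run pair 4 the ribosomal median lay at percentile 24.4, the respiratory chain median at 6.89 and the proteasome median at 30.7, all inside the central 95%. The respiratory chain median lay outside the central 95% in 11 of 15 alternatives and the proteasome median in 9 of 15. In the brightest 25% of features they lay at percentiles 17.7 and 16.9, and without the unnumbered pair the respiratory chain median lay at 19.8. The 11 glycolytic genes had a median of -0.34 (percentile 0.03), with Eno1 at -0.86 ± 1.29, Pgk1 at -0.70 ± 1.21, Tpi1 at 0.05 ± 0.57 and Aldoc at 0.19 ± 0.48. The glycolytic median was -0.56 in the unnumbered pair, 0.07 in pair 3 and -0.23 in pair 4, at percentiles 0.16, 55.2 and 14.0. Pgk1, like Eno1, was lowest in the unnumbered pair, at -1.92, against 0.50 in pair 3 and -0.68 in pair 4. Without the unnumbered pair, in which Eno1 lay in the block of lower features, the glycolytic median was -0.14 (percentile 2.11). With a local median subtracted it was -0.27 (percentile 0.03). The glycolytic median lay outside the central 95% in 14 of 14 alternatives, though inside it in pair 3 alone and in pair 4 alone. Respiratory chain genes (40, median -0.13, percentile 1.01) and proteasome genes (27, median -0.14, percentile 1.66) had medians of 0.09 and 0.21 in run pair 3 and were below 0 in the others. In the unnumbered pair, pair 3 and pair 4 the respiratory chain lay at percentiles 0.345, 84.4 and 0.435, and the proteasome at 8.42, 99.6 and 0.81. Ribosomal and proteasome genes thus lay above the central 95% in run pair 3 and below it in run pair 4. Uqcrc1 was at -0.53 ± 0.40, Sdhd at -0.27 ± 0.28, Ndufa12 at 0.27 ± 0.35 and Cox8a at 0.29 ± 0.28. Psmb4 was at -0.65 ± 0.46, Psmb1 at -0.53 ± 0.69 and Psmd11 at 0.48 ± 0.17, and Psma6 (1.40 ± 0.45) had raised neighbours.

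The other lists lay inside the central 95% of random lists in the mean of the run pairs. Myogenic regulators (8 genes, median -0.06, percentile 39.2) ran from Id1 at -0.30 and Mef2d at -0.24 to Fgfr1 at 0.06 and Tcf3 at 0.35. Muscle contractile genes (7, -0.13, 21.0) held Acta2 and Tpm3 (0.16) above and Tpm1 (-0.30) and Tpm2 (-0.21) below 0. Cell cycle genes (22, -0.05, 47.9) ran from Ccna2 (-0.31) and Mcm6 (-0.25) to Cdkn2c (0.25) and Ccnd1. Translation factors (26, -0.05, 44.0) ran from Eef1a1 (-0.47) and Eef1d (-0.35) to Eif4e and Eif3j1 (0.55). Chaperones (22, -0.12, 11.0) ran from Cct5 (-0.75 ± 1.21) and Hsp90aa1 (-0.35) to Cct6a (0.58) and Pdia4 (1.26), the last with raised neighbours. The chaperone median lay at percentile 99.7 in run pair 3 and 1.38 in run pair 4, and at 0.86 without run pair 3, 1.06 with the median of run pairs and 1.69 in the brightest 25% of features. Matrix genes (16, -0.10, 20.6) ran from Col4a2 (-0.28) and Mmp2 (-0.23) to Col6a1 (0.16) and Lum (0.45). Apoptosis regulators (8, 0.04, 84.6) ran from Birc5 (-0.26) and Cycs (-0.10) to Diablo (0.27) and Ptma, and lay at percentile 98.5 in run pair 3. Histones (5, -0.08, 36.3) ran from H2bc4 (-0.33) and H3f3b (-0.27) to H1f0 (0.02) and H2ax (0.16). Epithelial and liver markers (7, -0.14, 19.4) were all below 0, from Alb (-0.43) and Apoa1 (-0.28) to Krt18 (-0.04) and Ttr (just under 0), and lay at percentile 1.88 in the unnumbered pair. Fewer than 5 genes were measured for microRNA pathway (3), adipocyte (1), bone and cartilage (3), blood (2), neural (3) and small RNA (1) genes, and 0 for immunoglobulins.

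**Figure D3:**
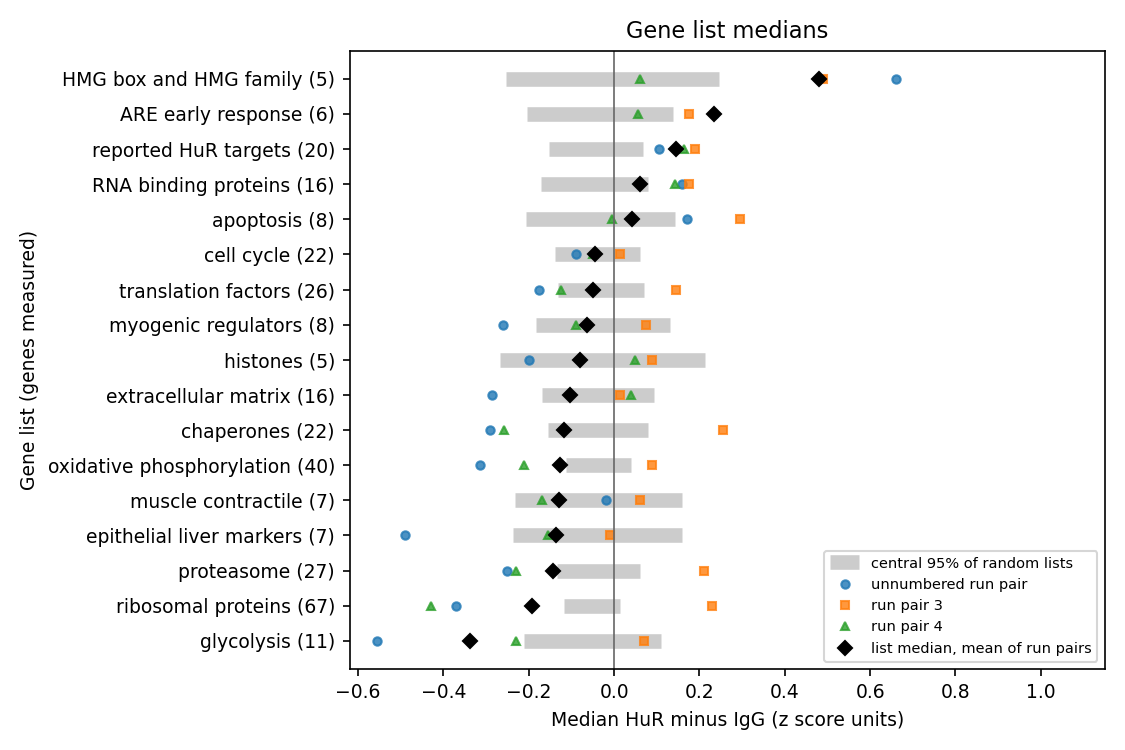
Median difference between HuR and IgG in z score units (horizontal axis) for 17 gene lists, with the number of genes measured. Diamonds are the mean of run pairs, other symbols are single run pairs, and grey bars are the central 95% of matched random lists for the mean of run pairs. Reported HuR targets lie at 0.15 and glycolysis at -0.34, and ribosomal proteins lie above 0 in run pair 3 alone.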

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

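The z score thresholds, run pairs, source plate, membrane and array section settings were chosen after seeing the data. The count of 132 higher features became 311 at a threshold of 0.6, 66 at 1.5, 57 without raised neighbours, 21 on the second section of the array and 126 to 191 with 1 run pair left out. The 8 lower features became 28 over all signal levels, 95 at 0.6, 0 at 1.5, 21 with the median of run pairs, 0 with a local median subtracted and 0 on the second section. Leaving out 1 run pair gave 8 to 78 lower features, with 78 without run pair 3 and 52 without run pair 4. The median of reported HuR targets was 0.03 over all signal levels, 0.23 in the brightest 25%, 0.30 on the second section and 0.09 to 0.22 with 1 run pair left out. High mobility group genes were at 0.11 over all signal levels. RNA-binding proteins were at -0.01 after quantile normalization, 0.00 with the scores as deposited, 0.03 over all signal levels, -0.04 in the brightest 25%, -0.02 by the brightest clone, 0.08 with the median of run pairs, 0.12 on the first section, -0.07 on the second, and 0.05 to 0.13 with 1 run pair left out. Muscle contractile genes were at 0.06 with the median of run pairs. With 1 run pair left out, early response genes were at 0.14 to 0.22 and apoptosis regulators at -0.11 to 0.18. With 1 run pair left out, the glycolytic median was -0.39 to -0.14, the chaperone median -0.30 to 0.01, the ribosomal median -0.41 to -0.05, the respiratory chain median -0.21 to -0.06 and the proteasome median -0.17 to -0.03. Of 1131 values of 89 named genes under the alternatives, 1100 moved by less than the spread between run pairs and 31 by more, and 0 changed the sign of a called value. For a gene with 1 clone, leaving out 1 run pair or taking their median cannot move the mean past that spread. For those settings the outcome was fixed in advance and does not show that a value holds without 1 pair. AA407151, for example, was at -3.35, 0.11 and -0.13 in the unnumbered pair, pair 3 and pair 4. The causes of the changes in this part were not tested. Not run were the background offset and the 1.5-fold and 3-fold thresholds, which need intensities, and the 3' UTR motif comparison. No paired analysis was possible because each antibody has 1 sample. Signal over background is unknown, so dim clones cannot be told from background.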

Other observations

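The tests in this part were all chosen after the results were seen, as were the genes named here outside the rule. Away from wells with raised neighbours, 43 clones of 32 genes were at least 1 unit higher with HuR. Besides Actb, Hmgb1, Pcbp2, Ptp4a1 and Set they included Ywhaz, a 14-3-3 adaptor protein, at 1.76 and 1.64 on 2 clones, while its other clones were at -0.08 and -0.16. Actr2, a subunit of the actin-nucleating Arp2/3 complex, was at 1.62 ± 0.20, with its other clone at 0.65. Prickle1, a planar polarity gene, was at 1.61 ± 0.23, and Cemip2 at 1.47 ± 0.24. Gsr, glutathione reductase, was at 1.29 ± 0.05 on 1 clone and 0.07 on another. Ptbp1, the polypyrimidine tract-binding protein, was just below the threshold at 0.93 ± 0.17, on plate 10 beside a Coq10b clone at 1.02. Clones without raised neighbours by the median rule could still adjoin high wells. Ube2l3, at 1.73 on plate 10, lay beside the wells of Actb, AV218468 and Ccnh.

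Of 103 annotation terms with 10 to 400 genes, 2 lay above and 7 below nearly all matched random lists, against 1.03 terms by chance. Terms share genes, so the 7 are not independent groups. Rpl9, for example, was the lowest member of protein biosynthesis, ribosome biogenesis, ribosome and cytosolic ribosome. Protein tyrosine phosphatases (10 genes) were led by Ptp4a1, Ptpn21 (0.59 ± 0.72) and Ptprs (0.53 ± 0.31). Their medians were 0.46, 0.06 and 0.12 in the unnumbered run pair, pair 3 and pair 4, at percentiles 99.8, 54.8 and 96.2, so the unnumbered pair alone lay outside the central 95%. Nucleolar genes (11) were led by Ddx21, an RNA helicase, at 0.70 ± 0.34, Acin1 at 0.39 and Pinx1 at 0.27, with Npm1, nucleophosmin, at -0.20. Their medians were 0.07, 0.14 and 0.02 in the same order, at percentiles 80.2, 84.3 and 80.1, so no single run pair lay outside the central 95% of random lists. Low terms covered glycolysis, the ribosome, hydrolases and the mitochondrion. Low positions were not particular to them: among the 9 broad function classes of the deposited table, energy and metabolism (median -0.12), signal transduction (-0.10), matrix and structural proteins (-0.11) and protein synthesis (-0.11) also lay at percentiles under 0.5. None of the low terms was low in run pair 3, where glycolysis lay at percentile 46.1, hydrolases at 75.4, the mitochondrion at 90.1 and the ribosome at 99.2, the last with a median of 0.21 against -0.37 and -0.47 in the others.

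High differences lay in neighbouring wells of few source plates, such as the region of plate 10 with AV218468, Ccnh, Fbxl5 and Heyl. Signal spreading between adjacent spots is argued against, since differences of adjacent spots correlated across features at 0.06 along rows and 0.12 along columns, much as for spots 4 apart (0.07 and 0.13), all from different plates. Spots 5 apart correlated at 0.52 along rows, where all pairs share a plate, and at 0.45 along columns, where 80% do. Clone DNA carried between wells is a candidate explanation that was not settled. Of 8 Actb wells, 7 had neighbours above wells at least 5 away. Wells of other genes were not compared in this way, and spots of 1 plate correlated over the whole array. The comparison thus cannot tell carried DNA from another cause shared by neighbouring wells. The neighbours' signal was below that of the far wells on plate 2 (0.06 against 0.49) and at E9 of plate 11 (0.73 against 1.02). It was above it for the other Actb wells. The excess in the 7 ran from 0.15 on plate 12 to 2.215 on plate 10, and Actb wells D9 and D10 of plate 18 adjoin and share neighbours. No named Actb clone lay on plate 45, which held 16 of the higher features, so the comparison of Actb wells does not cover that plate. Whether beta-actin is what was carried stays open: the share of such features higher in run 3 than in the unnumbered run was 94.4% on plate 10 and 6.67% on plates 41 and 45, against 9 of 10 actin clones, but 11.1%, 26.7% and 5 of 10 with plate medians subtracted, and 40.8% pooled over all plates before the split was made. HuR association of the annotated genes stays open too, because the other clones of 24 such genes had a median of 0.05 (upper quartile 0.15, 0 at least 1) and those of 18 genes without raised neighbours also had a low median, 0.12, though with an upper quartile of 0.85 and 4 at least 1. Of the other clones, 19 of 33 and 24 of 31 were in the brighter 50%, and a dimmer clone need not be able to show a difference of 1. The brighter ones alone had medians of -0.10 (16 genes, 0 at least 1) and 0.24 (15 genes, 4 at least 1), which leaves the question open as well.

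The 8 lower features, with Rragc, Cop1, Aen and Eno1 among their genes, lay in 1 block of 264 features. A local disturbance of 1 array may account for them, since all spots of the block had a median of -1.09 in the unnumbered run pair, 0.17 in run pair 3 and 0.00 in run pair 4. In the unnumbered run the block's HuR scores were at -0.96 relative to the other HuR runs, and its IgG scores at 0.10. Lower HuR association of these genes stays open, because the other run pairs opposed each other: the 8 features had a median of 0.17 in run pair 3 (0.05 to 0.46) and -0.60 in run pair 4 (-0.75 to -0.13), and their mean over both had a median of -0.17.

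Turning the sign of 1 run pair at a time gave at most 32 features past the threshold in 1 direction, against 132 higher features with the signs as measured, which was matched by 1 of the 4 sign patterns, the measured one. The 4 patterns are too few for a share under 0.05. They describe spread between runs counted as 1 sample per antibody. Because the runs are not stated to be separate immunoprecipitations, the patterns cannot be read as chance between immunoprecipitates.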
